A study of Caenorhabditis briggsae with 12 samples.

How the data were processed

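The libraries came from whole C. briggsae AF16 hermaphrodites kept at 20 °C on plates with E. coli OP50, per the labels' protocols. The animals were synchronised by bleaching, and adults were parted from larvae every second day by settling in buffer, with the remaining larvae picked off. RNA was extracted with Trizol and made into libraries with the TruSeq RNA kit v2, per the labels' protocols. The deposited file holds raw counts per gene, not normalised, with 1 column per library. Per the submitters' processing notes, STAR, featureCounts and MultiQC were used; their versions, the genome build, the annotation and the strand setting are not given in the sources used here. Reads shared between near-identical or overlapping genes may therefore have been split or dropped in ways that cannot be seen in the counts, so that single genes of such families are uncertain.

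Each library was assigned to a day and replicate from its title. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Counts of the same day differed beyond sampling noise in each pair (chi-square per degree of freedom of 3.56 to 239.5), so no library was counted as a repeat of another. The totals were 29696676 to 33732477 counts at day 1, 26471202 to 30458357 at day 3, 22703555 to 33079955 at day 6, and 14276540, 31861634 and 25821051 in replicates 1, 2 and 3 of day 9. A count of 0 allows a level of up to 0.089 CPM in the deepest library and 0.210 CPM in the shallowest, taking 3 counts as the limit. Such limits and the intervals given cover counting error only.

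The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the day as group, which left 15788 of 23169 genes; 2202 genes had 0 counts in all libraries, and the kept genes held at least 99.9% of the counts in each library. TMM factors were applied, and a model with 1 mean per day was fitted to all 12 libraries with robust quasi-likelihood dispersions, leaving 8 residual degrees of freedom. The common biological coefficient of variation was 0.341. The estimate of spread was shared between all days, and day 9 was the most variable of them. The p-values of comparisons with day 9 may therefore be too small. Quasi-likelihood F tests gave 5 comparisons and 1 test over the 4 days, and p-values were adjusted by the Benjamini-Hochberg method within each, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of F. CPM values are counts scaled to a common library total with the TMM factors applied, and log2 CPM a prior count of 2. The 10 most abundant genes were taken by mean CPM over all libraries. This group, the group at least 8-fold lower at day 3 and the overlap of opposite steps were chosen after seeing the data.

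The design, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Genes were named if called, with no overlap between the libraries compared and a mean of at least 10 CPM in the higher days, by the largest change, up to 2 higher and 2 lower per comparison for genes with an identifier only. A reference table of 22727 genes (assembly CB4) was searched for the identifiers and matched 0 of them. The files do not pair identifiers with names, and no name was guessed. For this reason the tests of gene lists fixed beforehand, among them vitellogenins, oocyte, sperm, larval and male genes, and the comparison of the X chromosome with the autosomes were not run, and no chromosome positions are given.

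The test was checked on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. Between days 1 and 3 it recovered 12% and 62% of them (15516 genes), between days 3 and 6 22% and 66% (15527 genes), between days 6 and 9 20% and 63% (15537 genes), between days 1 and 9 17% and 67% (15530 genes), and for days 6 and 9 against days 1 and 3 50% and 85% (15522 genes). False calls made up 5.13%, 1.12%, 1.19%, 4.55% and 4.26% of the calls, in that order. The simulation gave each gene the same spread on all days. In the data the median SD per gene on the log2 scale was 0.53 at day 9 and 0.10 to 0.18 on the other days. The simulated spread came from the fit of all 12 libraries, day 9 included. The simulated rates therefore do not carry over to the comparisons with day 9. They need not carry over to those among days 1, 3 and 6 either. Far more genes were called in most real comparisons than were changed in the simulation, so the real recovery may also differ. Many simulated 2-fold changes were missed, so a gene that was not called may have changed by 2-fold.

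The alternatives were median-of-ratios factors, upper-quartile scaling, no low-count filter, a filter of 1 CPM in at least 6 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), a fit of only the days compared, the replicate number as a block, an adjusted p under 0.01, a log2 fold change of at least 1, and each library left out in turn. Further settings added after seeing the data left out replicates 2 and 3 of day 9, all day 9 libraries, or the third libraries of days 3 and 6. Figures were drawn with matplotlib 3.10.9.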

Results

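Gene expression was measured by RNA-seq in whole hermaphrodites of Caenorhabditis briggsae, a self-fertile nematode related to C. elegans, using AF16, its wild-type laboratory strain. Animals were sampled on days 1, 3, 6 and 9 of adulthood, with 3 libraries per day and 12 libraries in all. The title of the series names a shift after reproduction, so each step in age was compared, then day 9 with day 1, then days 6 and 9 with days 1 and 3. The library totals ranged from 14276540 counts for day 9 replicate 1 to 33732477 for day 1 replicate 1. Of 23169 gene identifiers, 15788 were tested. The identifiers were paired with no gene symbols, so genes are given by identifier and groups of genes by their behaviour.

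Expression differed between the sampled days over a large part of the transcriptome. An F test over the 4 days called 10197 of the 15788 tested genes, or 64.6%. The first principal component of the log2 normalised counts (CPM) held 74.1% of the variance and set the day 1 libraries apart from those of days 3 and 6. The 3 day 1 libraries had the smallest spread, with a median standard deviation per gene of 0.10 on the log2 scale. This median was 0.15 at day 3, 0.18 at day 6 and 0.53 at day 9. Replicates 2 and 3 of day 9 correlated across genes at r = 0.994, and replicate 1 correlated with them at 0.834 and 0.812. Replicate 1 of day 9 lay nearer to day 6, with r up to 0.969, and the highest correlation between a day 9 library and a day 1 library was 0.939. Genes are not independent replicates, so these coefficients describe the libraries and carry no p-value.

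**Figure D1:**
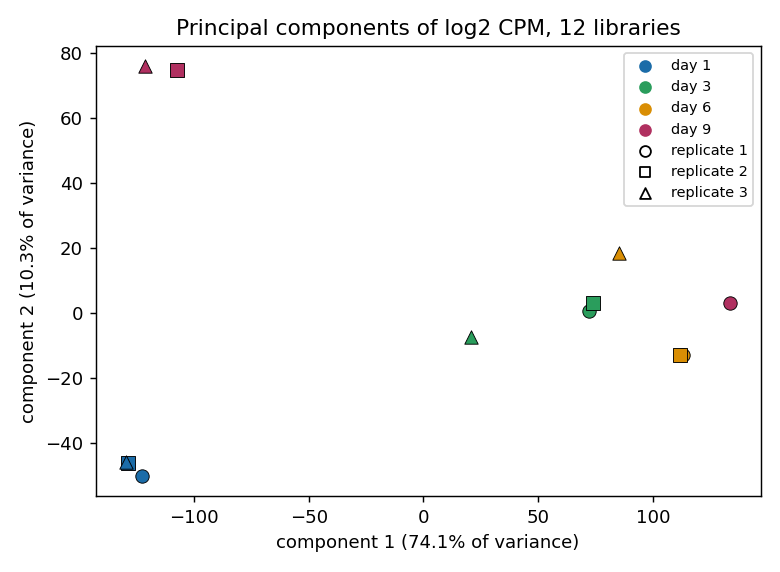
First and second principal components of log2 CPM for the 12 libraries, in units of the component score, with colour for the day and marker shape for the replicate. The first component holds 74.1% of the variance, and replicates 2 and 3 of day 9 lie at the day 1 end of it while replicate 1 lies at the opposite end, at 133.7.

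Between days 1 and 3, genes changed in both directions. At day 3, 4551 genes were higher and 2972 were lower than at day 1. The genes that fell did so more steeply, with a median log2 fold change of -2.22 against 0.78 for the genes that rose. The lower genes held 17.4% ± 0.39 of the counts at day 1 and 4.18% ± 0.37 at day 3 (SD, n = 3 each), and the higher genes held 44.5% ± 1.18 and 65.4% ± 1.54. Within the lower genes, 1287 fell at least 8-fold. Their median level in replicates 1, 2 and 3 of day 3 was 1.82%, 1.54% and 6.80% of the day 1 mean. The 10 genes most abundant over all libraries took 7.58% to 7.98% of the counts in the day 1 libraries and 11.9% to 13.98% in those of day 3, and 7 of them were called higher and 0 lower.

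Among called genes with no overlap between the libraries compared and a mean of at least 10 CPM in the higher days, the limits for naming a gene in this report, the largest falls from day 1 to day 3 were those of WBGene00032610 and WBGene00025941. WBGene00025941 went from 1705 ± 124 CPM to 12.8 ± 14.4 CPM (SD, n = 3 each), a log2 fold change of -7.06 ± 1.77 (SE) with an edgeR adjusted p of 0.00963. WBGene00032610 went from 11.5 ± 1.18 to 0.0775 ± 0.0996 CPM, a log2 fold change of -7.08 ± 1.25 (SE) with an edgeR adjusted p of 0.00253. Within these limits the largest rises were those of WBGene00034918, with a log2 fold change of 8.43 ± 1.66 (SE) and an edgeR adjusted p of 0.00375, and WBGene00026396, at 7.27 ± 1.33 and an edgeR adjusted p of 0.00294. Both rises came from replicates 1 and 2 of day 3. WBGene00034918 stood at 20.6 and 25.8 CPM there and at 0.190 CPM in replicate 3, and WBGene00026396 at 57.5 and 69.5 against 0.873 CPM. Neither was called by limma-voom. The 4 day 1 counts of WBGene00034918 were all in replicate 3. Leaving out single libraries gave it log2 fold changes of 7.66 (without day 3 replicate 2), 7.84 (day 1 replicate 1), 9.01 (day 3 replicate 3) and 11.73 (day 1 replicate 3), the last fitted against 0 counts and so no bound. The value of WBGene00026396 was 6.52 without day 3 replicate 2. The falls were larger without day 3 replicate 3, at -8.57 for WBGene00025941 and -8.79 for WBGene00032610.

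The balance of rises and falls between days 1 and 3 depended on scaling, the low-count filter, the tool and the libraries in the fit. Of the calls, 60.5% were higher with TMM scaling, 39.1% with median-of-ratios factors (2335 higher, 3641 lower) and 39.5% with upper-quartile scaling (2625 higher, 4018 lower), as the median log2 fold change of all genes went from 0.02 to -0.13 and -0.26. Without day 3 replicate 2 the higher genes numbered 1009, and with all day 9 libraries left out of the fit, a setting added after seeing the data, the lower genes numbered 5783. With only days 1 and 3 in the fit the lower genes numbered 6091. The higher genes numbered 1906 with no low-count filter and 2202 with a stricter one. DESeq2 called 3014 higher and 4128 lower genes.

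**Figure D2:**
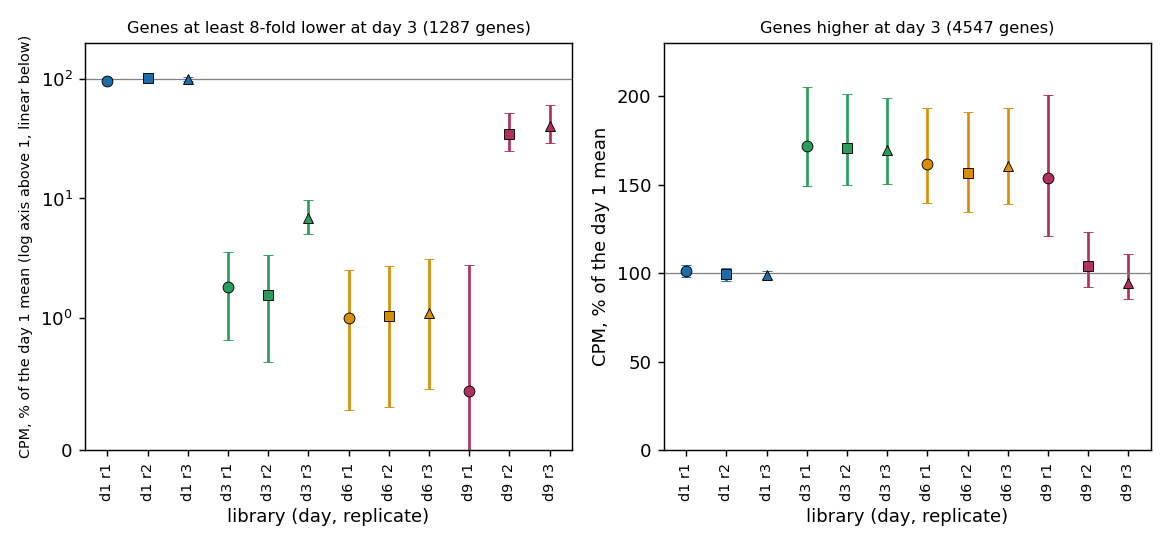
Median level (points) and quartiles (bars) of 2 groups of genes in each of the 12 libraries, in CPM as a percentage of the day 1 mean, with the day and replicate on the horizontal axis; the left vertical axis is logarithmic above 1 and linear below. The 1287 genes at least 8-fold lower at day 3 stay near 1% in the day 6 libraries and reach 34.4% and 40.3% in replicates 2 and 3 of day 9, and the 4547 higher genes with day 1 counts stand near 154% in day 9 replicate 1 and at 104.3% and 94.8% in the other libraries of that day.

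From day 3 to day 6, few genes were called in the fit of all 12 libraries. At day 6, 225 genes were higher and 85 were lower than at day 3. The median log2 fold changes were 1.48 and -1.50. Over all 15788 tested genes, the libraries of day 6 lay wholly above those of day 3 for 1651 genes and wholly below for 4653, where chance gives 10% of genes for both directions together. The direction of such counts follows any shift common to all genes, whose median log2 fold change was -0.13 here, -0.06 with median-of-ratios factors and 0.01 with a stricter low-count filter. The 225 higher genes held 0.372% ± 0.0083 of the counts at day 3 and 0.998% ± 0.062 at day 6 (SD, n = 3 each). The 1287 genes that had fallen at least 8-fold stayed low, at 0.998%, 1.03% and 1.0997% of the day 1 mean in the 3 day 6 libraries. Of the 10 most abundant genes, 0 were called higher and 1 lower.

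Within the limits for naming (no overlap, at least 10 CPM), the largest rise between days 3 and 6 was that of WBGene00035686, from 1.15 ± 0.34 to 27.6 ± 7.62 CPM (SD, n = 3 each), a log2 fold change of 4.58 ± 0.34 (SE) with an edgeR adjusted p of 0.00018. WBGene00027247 went from 4.02 ± 4.84 to 57.7, 59.2 and 69.05 CPM in the 3 day 6 libraries, a log2 fold change of 3.94 ± 0.79 (SE) with an edgeR adjusted p of 0.034. The largest falls within these limits were those of WBGene00029072, with a log2 fold change of -2.11 ± 0.46 (SE) and an edgeR adjusted p of 0.0464, and WBGene00041294, at -1.98 ± 0.35 and an edgeR adjusted p of 0.0202. The call of WBGene00029072 was lost when any single library of the 2 days was left out, and that of WBGene00041294 was lost without each of them except day 6 replicate 3. The call of WBGene00027247 was lost without day 3 replicate 1 or any day 6 library, and in a fit of only days 3 and 6, and its log2 fold change was 5.64 without day 3 replicate 3.

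The number of calls between days 3 and 6 differed with the libraries in the fit, the tool and the low-count filter. DESeq2 called 557 higher and 273 lower genes, a stricter filter gave 341 and 50, and with no filter the lower genes numbered 50. Fitting only days 3 and 6 gave 1031 higher and 750 lower genes, and leaving out all day 9 libraries, chosen after seeing the data, gave 1170 and 1806. The median log2 fold change of all genes went from -0.13 to 0.01 and -0.07, but the calls rose in both directions. Both settings took day 9, with a median SD per gene of 0.53 against 0.15 and 0.18 at days 3 and 6, out of the shared spread. The low number of calls in the fit of all 12 libraries may thus partly reflect the spread of day 9, which was not tested separately. Leaving out single libraries gave 84 higher genes (without day 3 replicate 1), 117 (day 3 replicate 2), or 142 (day 6 replicate 1). The lower genes then numbered 15, 21 and 9. Without day 3 replicate 3 there were 55 lower genes, and without day 6 replicate 2 there were 137 calls in both directions, 8 of them lower.

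From day 6 to day 9, most of the called rises showed some overlap between the libraries of these days, while most of the called falls showed none. At day 9, 4618 genes were called higher and 2443 lower than at day 6, with median log2 fold changes of 2.05 and -0.61. The higher genes held 4.76% ± 0.33 of the counts at day 6 and 14.7% ± 7.26 at day 9 (SD, n = 3 each). In 1867 of the higher genes, 40.4%, all 3 day 9 libraries lay above all 3 day 6 libraries, and in the other rises the libraries of these days overlapped. In 2243 of the lower genes, 91.8%, all 3 day 9 libraries lay below all 3 day 6 libraries. Over all 15788 tested genes, the day 9 libraries lay wholly above those of day 6 for 2283 and wholly below for 2652, where chance gives 10% for both directions together. The 10 most abundant genes together took 4.52%, 5.19% and 5.25% of the counts in the 3 day 9 libraries and 9.37% to 11.99% at day 6. Of these genes 6 were called lower, 0 higher and 4 were not called, with log2 fold changes from -2.25 to 0.22.

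The step from day 6 to day 9 ran against the step from day 1 to day 3 in replicates 2 and 3. The 1287 genes that had fallen at least 8-fold stood at 34.4% and 40.3% of their day 1 mean in replicates 2 and 3 of day 9, and at 0.445% in replicate 1. Of the 2972 genes lower at day 3, 2052 were called higher at day 9 than at day 6, where independent lists would share 869.3. Of the 4551 genes higher at day 3, 1847 were called lower at day 9, against 704.2. Calls in the same direction in both steps numbered 48 for falls and 78 for rises, against 459.9 and 1331. The steps share no library. Across genes their log2 fold changes correlated at r = -0.77 (Spearman -0.74). Set against the day 6 mean, each day 9 library gave a correlation with the first step of -0.73 (replicate 2), -0.74 (replicate 3) and 0.12 (replicate 1). Without day 9 replicate 1 these opposite calls numbered 4242 and 4712, and with replicate 1 as the lone day 9 library, a setting added after seeing the data, 443 and 690. They numbered 869 and 408 without day 6 replicate 1, 1000 and 459 without day 6 replicate 2, 1167 and 907 without day 9 replicate 2, and 1322 and 604 without day 9 replicate 3. The genes higher and then lower numbered 457 without day 3 replicate 2, 894 with median-of-ratios factors and 857 with upper-quartile scaling, and those lower and then higher 998 with limma-voom.

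**Figure D3:**
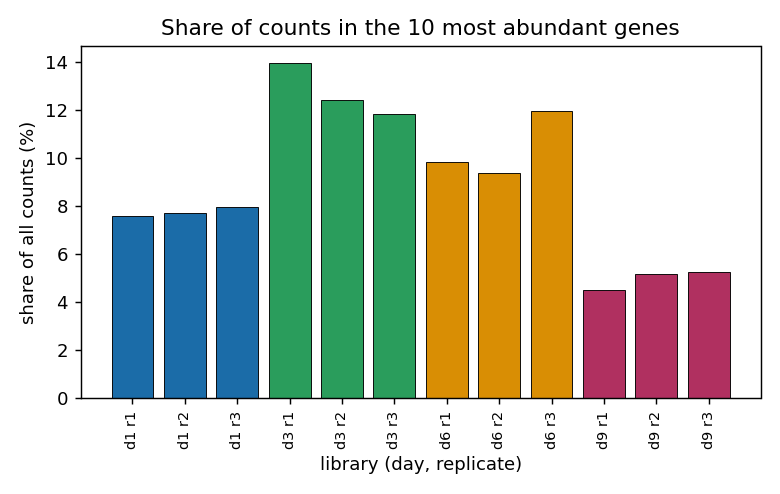
Share of all counts, in percent, taken in each of the 12 libraries by the 10 genes with the highest mean CPM over all libraries, 1 bar per library coloured by day. The 3 day 9 libraries lie between 4.52% and 5.25%, below the 7.58% to 7.98% of day 1 and the 9.37% to 11.99% of day 6.

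Within the limits for naming (no overlap, at least 10 CPM), the largest fall from day 6 to day 9 was that of WBGene00037431, from 14.8 ± 0.87 to 0.504 ± 0.358 CPM (SD, n = 3 each), a log2 fold change of -4.94 ± 0.48 (SE) with an edgeR adjusted p of 0.000385. WBGene00035686, which had risen between days 3 and 6, fell from 27.6 ± 7.62 to 2.11 ± 0.62 CPM, a log2 fold change of -3.69 ± 0.33 (SE) with an edgeR adjusted p of 0.000231. The largest rise within these limits was that of WBGene00029334, with a log2 fold change of 7.21 ± 1.68 (SE) and an edgeR adjusted p of 0.0116. It stood at 92.0 and 109.5 CPM in replicates 2 and 3 of day 9 and at 0.862 CPM in replicate 1, was not called without replicates 2 and 3, without day 6 replicate 1 or by limma-voom, and had stood at 24.5 ± 5.98 CPM at day 1. WBGene00024456, with a log2 fold change of 6.73 ± 1.30 (SE) and an edgeR adjusted p of 0.00685, stood at 47.1 CPM in replicate 1 and at 4.09 and 3.53 CPM in replicates 2 and 3, and its log2 fold change was 4.47 without replicate 1.

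The counts differed with the libraries in the fit. Fitting only the libraries of days 6 and 9 called 25 higher and 41 lower genes, and of the 4 named genes WBGene00035686 alone stayed called there. The fit of all 12 libraries shared a common spread between days. The median SD per gene was 0.53 at day 9 and 0.18 at day 6. In that fit the adjusted p of this step may therefore be too small. Without day 9 replicate 1 there were 6902 higher and 5478 lower genes. Without replicates 2 and 3 together, which leaves 1 library at day 9 that is assumed to vary like the other days, there were 1738 and 1763, of which 543 and 938 were among the original calls, and 1998 of the 4618 higher genes then had a negative fold change, against 0 of the 2443 lower genes with a positive one. The counts were 1488 and 998 without day 6 replicate 1, 1708 and 1051 without day 6 replicate 2, 2222 and 1206 without day 9 replicate 2, and 2207 and 1194 without day 9 replicate 3. Upper-quartile scaling made 78.1% of the calls higher (5603 and 1570 genes) in place of 65.4%, as the median log2 fold change of all genes went from 0.17 to 0.36, and limma-voom made 45.97% higher (2494 and 2931 genes).

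Over the whole span, 1088 genes were higher and 742 were lower at day 9 than at day 1. The median log2 fold changes were 1.29 and -1.45. The lower genes held 14.4% ± 0.14 of the counts at day 1 and 6.25% ± 0.64 at day 9, and the higher genes held 2.84% ± 0.0076 and 5.91% ± 0.73 (SD, n = 3 each). Of the 10 most abundant genes, 5 were called lower and 0 higher. WBGene00037431 fell from 53.0 ± 10.7 to 0.504 ± 0.358 CPM, a log2 fold change of -6.78 ± 0.51 (SE) with an edgeR adjusted p of 7.66e-05, and was lower in each of the 3 day 9 libraries. WBGene00025846 fell from 143.9 ± 9.84 to 8.55 ± 7.93 CPM, a log2 fold change of -4.05 ± 1.06 (SE) with an edgeR adjusted p of 0.0352, a call lost without any 1 of the day 1 libraries or day 9 replicate 2. This gene was already low before day 9, at 7.64 CPM at day 3 and 1.73 CPM at day 6. Its log2 fold change from day 1 to day 9 was -4.90 without day 9 replicate 3.

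Within the limits for naming (no overlap, at least 10 CPM), the largest rises from day 1 to day 9 were those of WBGene00024462 and WBGene00024459, which had 0 counts in the 3 day 1 libraries. The day 9 means were set against a floor of 3 counts over the day 1 libraries. That of WBGene00024462 was at least 2998-fold higher and that of WBGene00024459 at least 2020-fold, with edgeR adjusted p of 0.0089 and 0.0255. The level came largely from replicate 1 of day 9, so these limits hold for the mean and not for replicates 2 and 3. WBGene00024462 stood at 236.7 CPM there and at 17.04 and 16.2 CPM in replicates 2 and 3, and WBGene00024459 at 161.2 against 9.34 and 11.4 CPM. Without replicate 1 the fitted log2 fold changes of WBGene00024462 and WBGene00024459 went from 14.28 and 13.71 to 11.89 and 11.21, none of which is a bound, as day 1 was at 0 counts. The call of WBGene00024459 was lost without any 1 of the day 1 libraries, and neither gene was called by limma-voom.

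Fitting only days 1 and 9 called 246 higher and 155 lower genes, and of the 4 named genes WBGene00037431 alone stayed called there. The median SD per gene was 0.53 at day 9 and 0.10 at day 1. With the spread shared between days, the adjusted p of this comparison may also be too small. Without day 9 replicate 1 there were 3959 and 3207, and with replicate 1 as the lone day 9 library, assumed to vary like the other days, 4638 and 5591. The counts were 416 and 302 without day 1 replicate 1, 467 and 299 without day 1 replicate 2, and 447 and 289 without day 1 replicate 3, and the lower genes numbered 395 without day 9 replicate 2. Median-of-ratios factors made 41.5% of the calls higher (822 and 1161 genes) in place of 59.5%, as the median log2 fold change of all genes went from 0.13 to 0.03. DESeq2 gave 1290 and 1892 genes and limma-voom 1121 and 1308.

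For the shift after reproduction that the title names, the mean log2 level of days 6 and 9 was set against that of days 1 and 3. The log2 fold changes of this contrast therefore need not equal the ratio of the CPM means given, which are plain averages over 6 libraries. There were 878 genes higher and 652 lower in the later days, with median log2 fold changes of 1.02 and -0.93. The lower genes held 15.8% ± 0.76 of the counts in the earlier days and 10.4% ± 3.39 in the later days, and the higher genes held 2.11% ± 0.22 and 3.999% ± 0.53 (SD, n = 6 each). All 6 later libraries lay beyond all 6 earlier ones for 311 of the higher and 143 of the lower genes. Of the 10 most abundant genes, 6 were called lower and 0 higher. WBGene00037431 fell from 50.8 ± 8.80 to 7.67 ± 7.88 CPM, a log2 fold change of -4.25 ± 0.32 (SE) with an edgeR adjusted p of 8.39e-05. WBGene00032163 fell from 42.5 ± 23.6 to 5.32 ± 3.11 CPM, a log2 fold change of -2.79 ± 0.45 (SE) with an edgeR adjusted p of 0.0036. Its mean was 63.8 CPM at day 1, 21.2 at day 3, 4.65 at day 6 and 5.98 at day 9. Part of this fall thus lay between days 1 and 3.

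Within the limits for naming (no overlap, at least 10 CPM), the largest rises in the later days were again those of WBGene00024459 and WBGene00024462. WBGene00024459 had 0 counts in the 6 earlier libraries. Its mean in the later days was at least 1804-fold higher than a floor of 3 counts over the earlier libraries. Its edgeR adjusted p was 0.0181. WBGene00024462 had 1 count in the earlier libraries against 4813 in the later ones, a ratio of 5270 with an exact 95% interval for counting error of 945.5 to 208211, and an edgeR adjusted p of 0.00543. Both values rest largely on day 9 replicate 1, where WBGene00024459 stood at 161.2 CPM against 0.195 to 11.4 CPM in the other later libraries, and WBGene00024462 at 236.7 against 0.163 to 17.04 CPM. Without that library the fitted log2 fold changes of WBGene00024459 and WBGene00024462 went from 11.19 and 10.60 to 9.95 and 9.39, and that of WBGene00024462 was 11.62 without day 3 replicate 1, which held its 1 early count; none of these is a bound. At day 6 they stood at 1.86 ± 1.45 and 2.22 ± 1.78 CPM. Neither was called by limma-voom, and WBGene00024459 was not called without day 6 replicate 2.

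Without day 9 replicate 1 the later days had 2360 higher and 3543 lower genes, and with replicate 1 as the lone day 9 library, assumed to vary like the other days, 4802 and 5355. DESeq2 gave 1180 and 1744. The higher genes numbered 530, 571 and 558 without replicates 1, 2 and 3 of day 1. The lower genes numbered 357, 365 and 346 without these, 416, 414 and 379 without replicates 1, 2 and 3 of day 3, and 372 and 355 without replicates 1 and 2 of day 6.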

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

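The settings that left out day 9 replicates 2 and 3 together, all day 9 libraries, or the third libraries of days 3 and 6, and the overlap counts of opposite steps, were chosen after seeing the data. No named gene changed direction in any setting run: 278 fold changes of named genes stayed called and 44 were no longer called, while 138 counts stayed within 1.5 times the original and 115 did not. The fold changes tallied cover only genes that a setting tested. DESeq2 gave no adjusted p for WBGene00027247, WBGene00024456, WBGene00024462 and WBGene00024459, so they were left out there. The stricter low-count filter removed WBGene00034918, WBGene00032610, WBGene00024456, WBGene00024462 and WBGene00024459. The fit of only days 1 and 3 did not test WBGene00034918. The tests of gene lists and of the X chromosome were not run under any setting, since no identifier was matched. Depth limits mainly day 9 replicate 1, with 14276540 counts. Unless stated, the cause of a difference was not tested.

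Median-of-ratios factors gave 2335 genes higher at day 3 than day 1, 1161 lower at day 9 than day 1, and 894 higher at day 3 and then lower at day 9 than day 6. Upper-quartile scaling gave 2625 higher at day 3, 1570 lower at day 9 than day 6, and 857 of the latter overlap. With no low-count filter there were 1906 higher at day 3, 50 lower at day 6 than day 3, and an overlap of 787. The stricter filter gave 2202 higher at day 3, 341 higher and 50 lower at day 6, and an overlap of 928. DESeq2 gave 3014 higher at day 3, 557 higher and 273 lower at day 6 than day 3, 1892 lower at day 9 than day 1, and 1744 lower in days 6 and 9 than in days 1 and 3. With limma-voom 2494 genes were higher at day 9 than day 6, 1308 lower at day 9 than day 1, and 998 lower at day 3 and then higher at day 9.

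Fitting only the days compared gave 6091 lower at day 3, 1031 higher and 750 lower at day 6, 25 higher and 41 lower at day 9 than day 6, and 246 higher and 155 lower at day 9 than day 1. An adjusted p under 0.01, stricter by construction, left 2429 higher and 1731 lower at day 3, 79 and 10 at day 6, 817 and 766 at day 9 against day 6, 407 and 240 against day 1, 408 and 233 in the later days, 5433 over the 4 days, and overlaps of 301 (lower, then higher) and 504 (higher, then lower). A log2 fold change of at least 1 left 1207 higher at day 3, 393 lower at day 9 than day 6, 699 higher and 493 lower than day 1, 446 higher and 298 lower in the later days, and an overlap of 136.

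The replicate block gave 140 higher and 35 lower genes at day 6 than day 3 and left the other counts within 1.5 times; WBGene00027247 and WBGene00029072 were not called. Same-numbered libraries of different days had residual correlations of -0.35 to 0.48 (mean 0.11), above 0.1 in 9 of 18 pairs. They were 0.097 to 0.362 for replicate 1, 0.042 to 0.477 for replicate 3 and -0.353 to 0.043 for replicate 2. Whether the numbers pair the libraries thus stays open.

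Without day 9 replicates 2 and 3 together, where the lone day 9 library is assumed to vary like the other days, 6250 genes were lower at day 3, 1627 higher and 1290 lower at day 6, 1738 higher at day 9 than day 6, 4638 higher and 5591 lower than day 1, 4802 higher and 5355 lower in the later days, and the overlaps were 443 and 690. With all day 9 libraries left out, 5783 were lower at day 3, and 1170 higher and 1806 lower at day 6. Leaving out the third libraries of days 3 and 6 left the counts of these steps within 1.5 times.

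Leaving out in turn each library of the days compared, and no library of other days, gave 1009 to 3634 genes higher and 2133 to 2490 lower at day 3 than day 1, 84 to 215 higher and 8 to 107 lower at day 6 than day 3, 1488 to 6902 higher and 998 to 5478 lower at day 9 than day 6, and 416 to 3959 higher and 289 to 3207 lower at day 9 than day 1. Over all 12 libraries the ranges were 530 to 2360 higher and 346 to 3543 lower in the later days, 6982 to 14196 over the 4 days, 869 to 4242 for the overlap lower then higher, and 408 to 4712 for higher then lower. The highest value came without day 9 replicate 1 in each comparison with that day, in the test over the 4 days and in both overlaps.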

Other observations

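The tests of labels and swaps, those of day 3 replicate 3, the group of genes shared by the day 9 libraries, the wider base and spread for the mixture and the pairings of whole days were chosen only after the result was seen.

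In 524 genes all 3 day 9 libraries lay above all 9 other libraries and in 548 all 3 lay below. The higher set took 2.14%, 2.14% and 2.15% of the counts in replicates 1, 2 and 3 of day 9 and 0.910% to 1.16% in the other libraries. The lower set took 7.31%, 7.80% and 7.77%, against 11.7% to 18.1% elsewhere. The sets were selected by this difference, so the shares give their size and test nothing.

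Replicates 2 and 3 of day 9 stood apart from replicate 1, with 7030 genes (44.5%) at least 2-fold apart, 5304 of them higher in replicates 2 and 3, and 223 genes apart between those libraries. Wrong labels were argued against by the 1072 genes shared by the 3 libraries: 6 triples with a day 3 or day 6 library in place of replicate 1 reached at most 303, 3 triples with day 1 libraries in place of replicates 2 and 3 at most 127, and 18 triples replacing all 3 labels at most 126. A swap stays open, because 1 of 27 single swaps, that of day 9 replicate 1 with day 6 replicate 3, raised the sum of such genes over the 4 days from 7432 to 7939, by giving day 6 2408 in place of 1132 although day 9 then had 303; triples that join day 1 libraries to replicates 2 and 3 of day 9 also exceeded 1072, up to 2251 genes. Depth is an unlikely cause, as 97.04% of the 7030 genes stayed apart after thinning. For day 1-like RNA added to a replicate 1-like state, 917 genes (5.81%) were over 2 times above both. This exceeded the 5% set beforehand by more than the SD of 0.47 between replicates 2 and 3 taken alone. For an unmixed state between replicate 1 and day 6 the share was 5.42% (856 genes), above 5% by less than its SD of 0.43. The 5% was a chosen allowance, and the SD is not the error of a share in both replicates. The rule therefore cannot separate these mixtures. An exact mixture puts no gene above its parts, and only 223 genes were 2-fold apart between replicates 2 and 3. For parts like the libraries measured here, the 917 and 856 genes thus argue against an exact mixture as the whole cause, but not as part of it. The unmixed state and the added RNA were not measured, so mixtures of other parts stay open. By the rule, the mixture with a state between replicate 1 and day 6 stays undecided. Animals of another stage or sex could not be tested, since 0 identifiers were paired with markers, and no biological explanation was tested because the design gives no group within day 9.

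Day 3 replicate 3 lay toward day 1. Among the 551 genes at least 8-fold lower at day 3 that had a mean of at least 10 CPM at day 1, its excess over replicates 1 and 2 had a median of 4.52% of the day 1 level, and the 75th percentile was 1.64 times the 25th, which is consistent with a small share of day 1-like RNA in this library as a hypothesis. Such a share cannot be the whole cause, because 13 genes were at least 10-fold lower in replicate 3 than in both others, against 0 for each other library in its place. No biological explanation was tested, since the design gives no group within day 3.

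Other splits of the samples bore on the counts of called genes as follows. With 3 libraries against 3 there are 10 splits, the real one included, too few for a share under 0.05. In each step only the real split, 1 of 10, reached the real count. The real count and the highest other were 7523 and 0 for day 3 against day 1, 310 and 0 for day 6 against day 3, 7061 and 5583 for day 9 against day 6, and 1830 and 0 for day 9 against day 1. The split with 5583 genes exchanged day 9 replicate 1 with day 6 replicate 3. The other splits mix libraries of both days in each group. Their counts of 0 therefore show only that libraries of the same day resemble each other. For days 6 and 9 against days 1 and 3, 2 of 100 splits reached 1530 genes, the real one included. The highest other split called 8654 genes and set days 3 and 6 against days 1 and 9. The random splits mostly scatter the libraries of a day, which resemble each other, so low counts follow whatever the contrast. They therefore cannot decide whether chance explains the count. Nor do they show that the contrast exceeds other pairings of days. Of the 3 pairings of whole days, days 3 and 6 against the others called 10537 genes and days 3 and 9 against the others 366, which points to a structure of the samples larger than the contrast itself. For the test over the 4 days, only the real grouping, 1 of 100, reached 10197 genes, with 8555 as the highest other. Random splits mix the days within a group, so this shows only that libraries of the same day resemble each other. Chance differences between cultures are not excluded, because the labels do not say that the replicates came from separate cultures.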
